A study of Mus musculus with 8 samples.

How the data were processed

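Whole livers of 8 mice were measured on 1-colour Agilent mouse arrays (design 026655), 1 array per mouse. Per the labels, 4 groups of 2 mice combine sex with genotype. AKP mice carry an activated oncogene and mutant p53 (R172H) in the liver, and AKP::Keap1 mice also lack Keap1 there. Per the labels' protocols, total RNA was extracted and 500 ng of it was labelled with Cy3. The deposited scanner files hold linear intensity values per spot, which per the file headers come from Agilent Feature Extraction 10.7.3.1 with an mm9 annotation, whereas the submitters' processing notes name version 10.1. The column used is the processed signal, an intensity after the software's own background subtraction. The deposited series matrix holds the same processed signals, equal in 355176 of 355176 values compared, so its intensity values carry no scaling between arrays.

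Each array has 44397 spots, of which 1377 are controls and were left out, as were spots marked as outliers. Log2 signals of the spots of one probe were averaged, which gave 39429 probes. A probe was named through its RefSeq accession in a table of assembly GRCm38.p6 without versions on either side. In this way 26055 probes received 1 of 19751 gene symbols and 13374 stayed unnamed and were not used. Because that assembly is not the one in the file headers, no coordinates are given. Values are log2 of the processed signal minus each array's 75th percentile. A probe was kept if it was well above background on at least 2 of 8 arrays, and the probe with the highest mean stood for its gene. This left 15834 genes.

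Differences were tested with limma 3.58.1 in R 4.3.3, in a model with 1 mean per group and moderated spreads shared over all 8 arrays. The contrasts were genotype (AKP::Keap1 minus AKP, as the mean over both sexes and within each sex), the genotype by sex interaction (the female difference minus the male difference) and sex (female minus male, as the mean over both genotypes). A gene was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. All adjusted p-values of genes come from limma, errors of log2 differences are standard errors of that fit, and n is 2 mice per group. Of 40 gene lists fixed before the data were examined, 38 were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The other two, targeted genes and sex chromosome genes, are given gene by gene. Camera with an estimated correlation and fry were run beside it.

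Genes named for a contrast follow rules set at the same time. The targeted and sex chromosome genes are always named. For genotype and for sex these are the 10 largest rises and 10 largest falls among called genes that were well above background on every array of a side and changed the same way, without overlap of arrays, within each sex or each genotype. For each sex alone and for the interaction they are the 5 largest rises and 5 largest falls, without the stratum condition. Clone and predicted names were skipped, and some genes that meet the rules are not reported here. For each list, up to 3 members that rose and up to 3 that fell with the smallest adjusted p were eligible, up to 2 members with the smallest p where none was called, and further members where they explain a count. A gene that was not well above background on any array of one side has only a bound there. Its change is given as "at least N-fold": the bright side's mean against the dim side's mean, where each dim value was raised to the lowest signal among probes well above background on that array. The rules rank by fitted differences, which for such genes include signals below background, so their place in an order is not a measured rank. Setting such genes at their bound was done for list medians by genotype over both sexes and by sex. Of those printed below, the medians moved for proliferation by genotype, from 1.48 to 1.43, and for B and plasma cells by sex, from 0.76 to 0.75. List medians within each sex and in the interaction were not recomputed at bounds.

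The fit was tested on simulated data with the real genes' means and spreads and 200 changed genes per draw, in 5 draws over 15834 genes. A simulated 2-fold change was recovered for 71.9% of genes by genotype, 30.1% in males, 29.6% in females, 1.79% for the interaction and 71.3% by sex. A simulated 4-fold change was recovered for 93.9%, 82.4%, 86.1%, 60.0% and 95.8% of genes. False calls made up 7.63%, 7.43%, 2.76%, 7.69% and 6.43% of the calls. Every real contrast called more than 200 genes, and the simulated noise was independent between genes, without slide or brightness effects. These rates therefore check the fit and do not carry over to the real contrasts.

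Each of the 4 slides holds 1 group, and males and females were scanned on 2 different days. Slide and group therefore cannot be told apart in any comparison of single groups. No slide holds both genotypes or both sexes, so averages over groups also compare different slides. The spread in the model with 1 mean per group comes from mice on the same slide. Its p-values therefore leave out any spread between slides. Scan day and sex cannot be told apart at all. The genotype differences within males and within females are also the differences within each scan day. The number of arrays limits the precision. Alternatives covered the scaling, the filter, the probe rule, the fit, the replicate number as a block and leaving out each array. An alternative planned on the mean signal was run on the median signal, because the files hold no mean signal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.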

Results

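The series asks how loss of Keap1, which activates the transcription factor Nrf2, acts on bile duct cancer driven by an oncogene and mutant p53 in mouse liver. RNA of whole liver from 2 AKP males, 2 AKP::Keap1 males, 2 AKP females and 2 AKP::Keap1 females was profiled. Between 65.7% and 70.7% of the spots were well above background per array, and no spot was saturated. Replicates correlated at 0.9895 to 0.9919 across genes, which are not independent replicates. The first principal component, with 46.3% of the variance, separated the genotypes, and the second, with 31.0%, the sexes.

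Keap1, the adaptor that targets Nrf2 for degradation, was lower in all 4 AKP::Keap1 mice than in any AKP mouse. Its level, on the log2 scale relative to the array's 75th percentile, was 1.99 ± 0.22 (SD, n = 2) in AKP males and -1.37 ± 0.04 in AKP::Keap1 males. In females it was 1.72 ± 0.06 in AKP and -0.62 ± 0.14 in AKP::Keap1 (SD, n = 2). The difference was -2.85 ± 0.11 (SE, adjusted p = 0.00018), a 7.22-fold fall, with -3.36 ± 0.15 in males and -2.34 ± 0.15 in females. The files do not say whether the probe lies in the deleted part of the gene. The mRNA of Nrf2 itself, Nfe2l2, fell by 0.40 ± 0.10 (adjusted p = 0.024). Trp53 (0.12 ± 0.11, adjusted p = 0.42) was not called and had -0.11 after quantile normalization and -0.12 after a shift to the array median. The Trp53 probe does not tell the mutant from the normal allele.

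**Figure D1:**
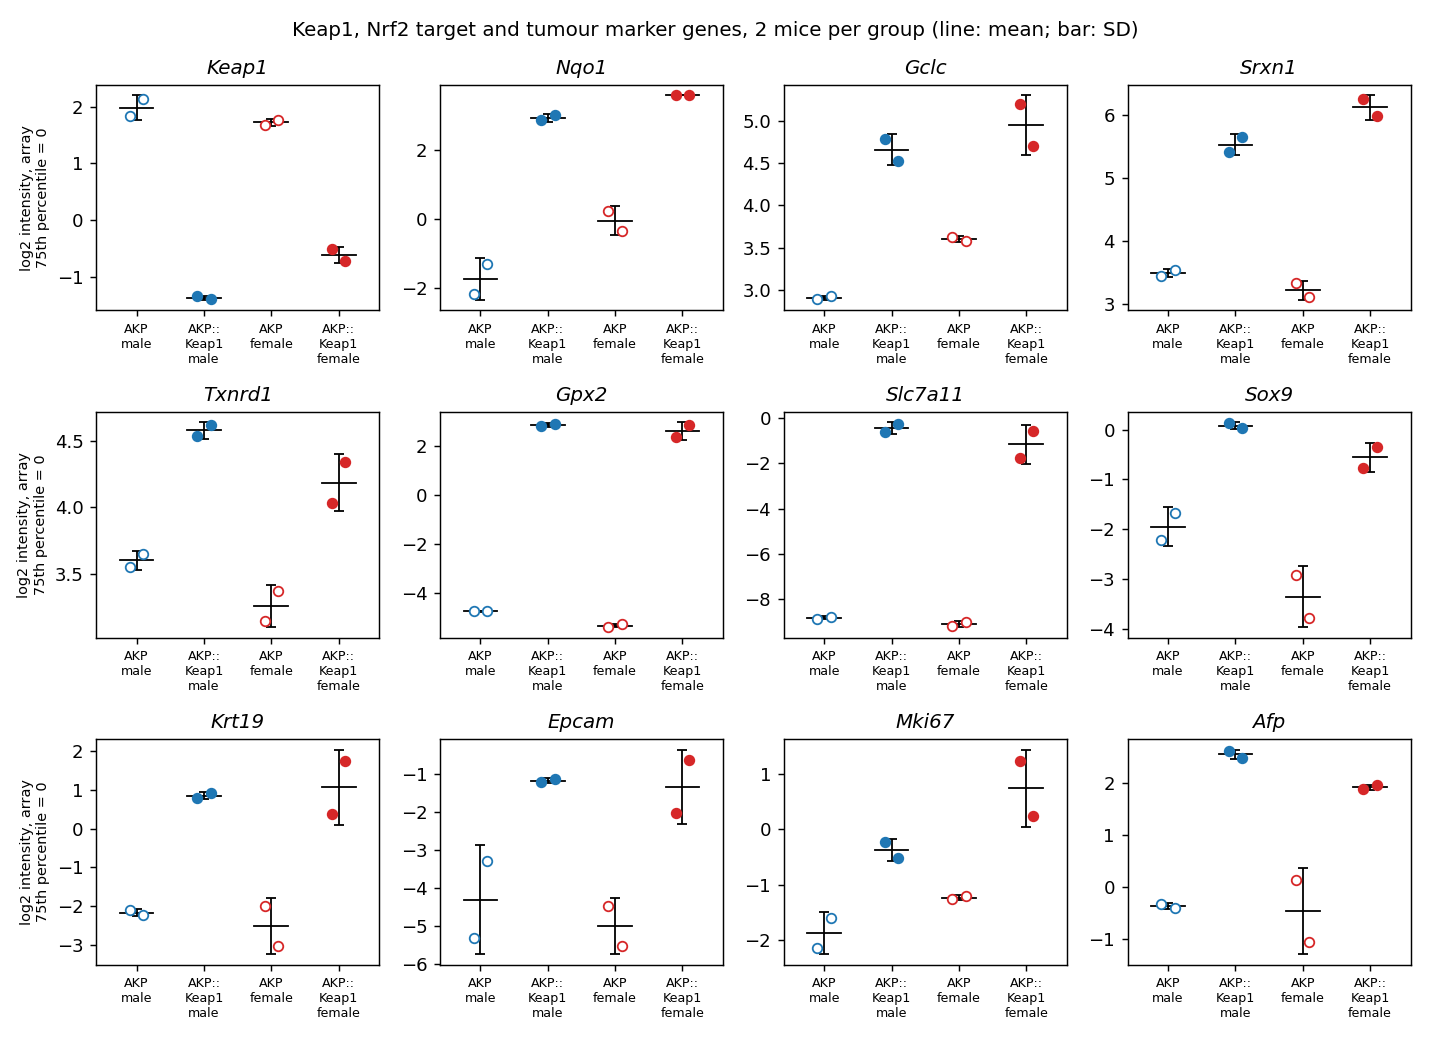
Log2 intensity per array, relative to the array's 75th percentile, of 12 genes in the 4 groups. Points are mice (2 per group), lines are means and bars are SDs, and Keap1 lies lower and the other genes shown lie higher in every AKP::Keap1 mouse than in the AKP mice of the same sex.

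Between genotypes, averaged over the sexes, 6185 of 15834 genes were called, 3456 higher and 2729 lower in AKP::Keap1, and 1886 of them changed at least 2-fold (1539 higher, 347 lower). The dimmest 1584 of all genes had a median of 0.50 in this contrast (0.19 after quantile normalization), and the brightest 1584 had -0.16. The excess of 2-fold rises is therefore not free of a trend with brightness. Of 1443 called genes with several kept probes, 246 had probes of opposite sign, so their direction rests on the probe used. Genes with the largest fitted rises included S100b, a calcium-binding protein (at least 151-fold, adjusted p = 6.6e-05), and Gsta1, a glutathione transferase (8.26 ± 0.50, adjusted p = 0.00044). They were followed by the neutrophil attractant Cxcl5 (8.20 ± 0.43), the cystine transporter Slc7a11 (at least 60.9-fold), Tinag (8.05 ± 0.37), the glutathione peroxidase Gpx2 (7.76 ± 0.13) and the carbonyl reductase Cbr3 (7.50 ± 0.13). The trefoil peptide Tff2 (7.45 ± 0.50), the GABA receptor subunit Gabrp (7.15 ± 0.37) and Fam83e (at least 49.7-fold) complete the 10. Genes with the largest fitted falls included the fatty acid hydroxylase Cyp4a14 (-5.61 ± 1.19, adjusted p = 0.013), the endothelial lipase Lipg (at least 3.01-fold), Kcnk10 (at least 4.17-fold), Keap1, Dmrta1 (at least 2.44-fold) and Slc25a30 (-2.68 ± 0.43). The leptin receptor Lepr (-2.62 ± 0.44, with probes from -2.92 to -0.63), the lipid droplet protein Pnpla3 (-2.49 ± 0.31), Cyp4a32 (-2.45 ± 0.57) and the transcription factor Onecut1 (-2.39 ± 0.59) also fell. Tinag and Tff2 were above background on 1 of 4 AKP arrays, so that their sizes are uncertain. Cyp4a14 was uneven among the AKP males, with an SD of 4.02 on the log2 scale. Gst and Cyp genes belong to families of similar sequence, so cross-hybridisation leaves their single values uncertain.

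Genes that Nrf2 is known to drive rose together. Among 17 genes of glutathione and thioredoxin metabolism, 12 rose, 1 fell and 4 were not called (14 rose and 1 fell adjusted over the list alone), with a median of 0.87. Gpx2, Slc7a11 and Pgd (1.78 ± 0.08) led, with Srxn1 (2.47 ± 0.11), Gclc, the catalytic subunit of the first enzyme of glutathione synthesis (1.55 ± 0.13), G6pdx (1.14 ± 0.19) and Txnrd1 (0.96 ± 0.11). Isocitrate dehydrogenase Idh1 fell in the mean over the sexes (-0.79 ± 0.09), with a called interaction of -1.25. Gclm was not called (0.43 ± 0.15, adjusted p = 0.062). Of 37 detoxification and transport genes, 25 rose, 0 fell and 12 were not called (26 rose and 1 fell adjusted over the list alone), with a median of 1.39. Cbr3, the efflux pump Abcc4 (4.94 ± 0.15), Gstm3 (4.22 ± 0.16) and the quinone reductase Nqo1 (4.17 ± 0.22) led, while heme oxygenase Hmox1 was not called (-0.22 ± 0.23, adjusted p = 0.47, and 0.093 with series matrix values). Both lists were called by camera (adjusted p = 1.6e-06 and 1.1e-09), each with adjusted p = 0.606 with an estimated correlation.

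Markers of bile duct epithelium were higher in AKP::Keap1 livers. Of 28 biliary genes, 22 rose, 1 fell and 5 were not called (23 rose and 1 fell adjusted over the list alone), with a median of 2.12. They included Ggt1 (at least 14.6-fold), Anxa13 (4.73 ± 0.29), Tspan8 (5.65 ± 0.37), the keratins Krt19 (3.30 ± 0.36) and Krt7 (2.95 ± 0.34), Epcam (3.41 ± 0.54), osteopontin Spp1 (3.28 ± 0.40) and the duct regulator Sox9 (2.42 ± 0.23). Onecut1 was the member that fell. The list was called (adjusted p = 1.5e-07, and adjusted p = 0.606 with an estimated correlation). In the list of gastric and pancreatobiliary mucin-type epithelium, 6 of 12 genes rose, 0 fell and 6 were not called (7 rose adjusted over the list alone), led by Tff2, Muc13 (0.99 ± 0.13) and Muc4 (1.47 ± 0.39, above background on 1 of 4 AKP arrays). Its call (median 0.68, adjusted p = 0.040, and adjusted p = 0.606 with an estimated correlation) was lost without AKP male 2, AKP::Keap1 male 2 or AKP female 1, where the medians were 0.39, 0.46 and 0.81, and under 4 other settings.

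Fetal liver and tumour markers and cell cycle genes were higher as well. Of 16 fetal and tumour genes, 12 rose, 0 fell and 4 were not called (13 rose adjusted over the list alone), with a median of 0.998. Examples are Ly6d (4.46 ± 0.19), Scd2 (2.63 ± 0.23), alpha-fetoprotein Afp (2.65 ± 0.25) and the cell cycle inhibitor Cdkn2a (3.27 ± 0.42). Of 27 proliferation genes, 22 rose, 0 fell and 5 were not called (23 rose adjusted over the list alone), with a median of 1.48. They included the mitotic kinase Aurkb (at least 1.89-fold), the replication helicase subunit Mcm5, Cdk1 (2.07 ± 0.22) and Mki67 (1.74 ± 0.25). Camera called both lists (adjusted p = 0.00027 and 2.9e-08), each with adjusted p = 0.606 with an estimated correlation.

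Genes of hepatocyte function were lower. Of 30 hepatocyte identity genes, 0 rose, 14 fell and 16 were not called (24 fell adjusted over the list alone), with a median of -0.44. Tyrosine catabolism gene Hpd (-0.63 ± 0.09), urea cycle enzyme Cps1 (-1.23 ± 0.20), Cyp2c29 (-0.64 ± 0.12) and the regulators Cebpa (-0.85 ± 0.16) and Hnf4a (-0.48 ± 0.12) fell, and albumin Alb was not called (-0.31 ± 0.13, adjusted p = 0.10). The list was called (adjusted p = 1.8e-06, and adjusted p = 0.606 with an estimated correlation). The brightest 1584 of all genes had a median of -0.16 in the same contrast. Of 24 genes of fatty acid oxidation and PPAR alpha, 0 rose, 14 fell and 10 were not called (16 fell adjusted over the list alone), with a median of -0.70. Acadl (-0.83 ± 0.11), Hadhb (-0.71 ± 0.12), the carnitine carrier Slc25a20 (-0.83 ± 0.14) and Cyp4a14 were among them. Of 20 lipogenesis genes, 3 rose, 11 fell and 6 were not called (4 rose and 13 fell adjusted over the list alone), with a median of -0.75. Fatty acid synthase Fasn (-1.45 ± 0.15), Gpam (-1.13 ± 0.12), Elovl6 (-1.64 ± 0.20) and the desaturase Scd1 (-1.63 ± 0.23) fell. The fatty acid uptake receptor Cd36 (0.88 ± 0.10), the lipid droplet protein Cidea (3.18 ± 0.39) and Pparg (0.62 ± 0.11) rose. Pparg had a called interaction of -1.49, so its mean over the sexes does not hold for each sex. These lists were called at adjusted p = 1.7e-05 and 0.0071, each with adjusted p = 0.624 with an estimated correlation, and the lipogenesis call ended after a shift to the array median.

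Markers of other cell types moved apart. Of 26 stellate cell and fibrosis genes, 14 rose, 3 fell and 9 were not called (16 rose and 3 fell adjusted over the list alone), with a median of 0.46. The protease inhibitor Timp1 (2.49 ± 0.14), the collagen Col3a1 (1.22 ± 0.10) and Tagln (1.21 ± 0.12) rose, and Reln (-1.33 ± 0.20), Postn (-0.31 ± 0.08, and 0.0023 with series matrix values) and Dcn (-0.40 ± 0.12) fell. Of 23 macrophage and monocyte genes, 13 rose, 1 fell and 9 were not called (13 rose and 1 fell adjusted over the list alone), with a median of 0.66. Among them Cx3cr1 (3.44 ± 0.35), Trem2 (2.61 ± 0.32), the monocyte receptor Ccr2 (1.57 ± 0.17) and Cd9 (1.08 ± 0.09) rose, and Fcgr3 (-0.49 ± 0.12) fell. Of 15 neutrophil genes, 9 rose, 0 fell and 6 were not called (9 rose adjusted over the list alone), with a median of 1.94, led by S100a8 (2.97 ± 0.22), Elane (2.19 ± 0.17) and S100a9 (2.62 ± 0.24). Of 21 cytokine and chemokine genes, 10 rose, 0 fell and 11 were not called (10 rose adjusted over the list alone), with a median of 0.52, among them Cxcl5, Ccl2 (3.34 ± 0.38) and Tnf (2.30 ± 0.38). Camera called these lists at adjusted p = 0.0014, 0.00038, 0.00073 and 0.013. In the same order the adjusted p was 0.624, 0.636, 0.606 and 0.636 with an estimated correlation. The cytokine call ended with series matrix values.

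Camera did not call the resident Kupffer cell and endothelial lists, while fry called the endothelial list (adjusted p = 0.013). Of 11 Kupffer cell genes, 0 rose, 3 fell and 8 were not called (2 fell adjusted over the list alone), with a median of -0.07. Fabp7 (-0.55 ± 0.10), the scavenger receptor Cd163 (-1.95 ± 0.49, above background on 3 of 4 AKP::Keap1 arrays) and Nr1h3 (-0.30 ± 0.09, and 0.0093 with series matrix values) fell. Of 17 endothelial genes, 1 rose, 7 fell and 9 were not called (1 rose and 7 fell adjusted over the list alone), with a median of -0.21. Cd34 rose (1.27 ± 0.21, other probe 0.36), and Clec4g (-0.50 ± 0.09), Tek (-0.77 ± 0.16) and Pecam1 (-0.44 ± 0.09) fell. The T and NK cell list (19 genes, 6 rose, 0 fell, median 0.33) and the B and plasma cell list (11 genes, 2 rose, 0 fell, median 0.45) were called by neither (6 and 1 rose adjusted over the list alone).

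Camera called 13 of 38 lists by genotype (10 up, 3 down), fry 17 including these 13 and the pericentral, endothelial, muscle and glycolysis lists, and camera with an estimated correlation 0, where 1 list had an unadjusted p below 0.05. With the slide as a random block in an additive model, chosen after seeing the data, 3310 genes were called (2136 higher, 1174 lower). The split of calls depends on the scaling. After a shift to the array median, 2372 genes were higher and 6372 lower, with all genes shifted by a median of -0.25. With unscaled series matrix values 5703 were higher and 646 lower, with a shift of 0.31. After quantile normalization 2956 were higher and 2848 lower.

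**Figure D2:**
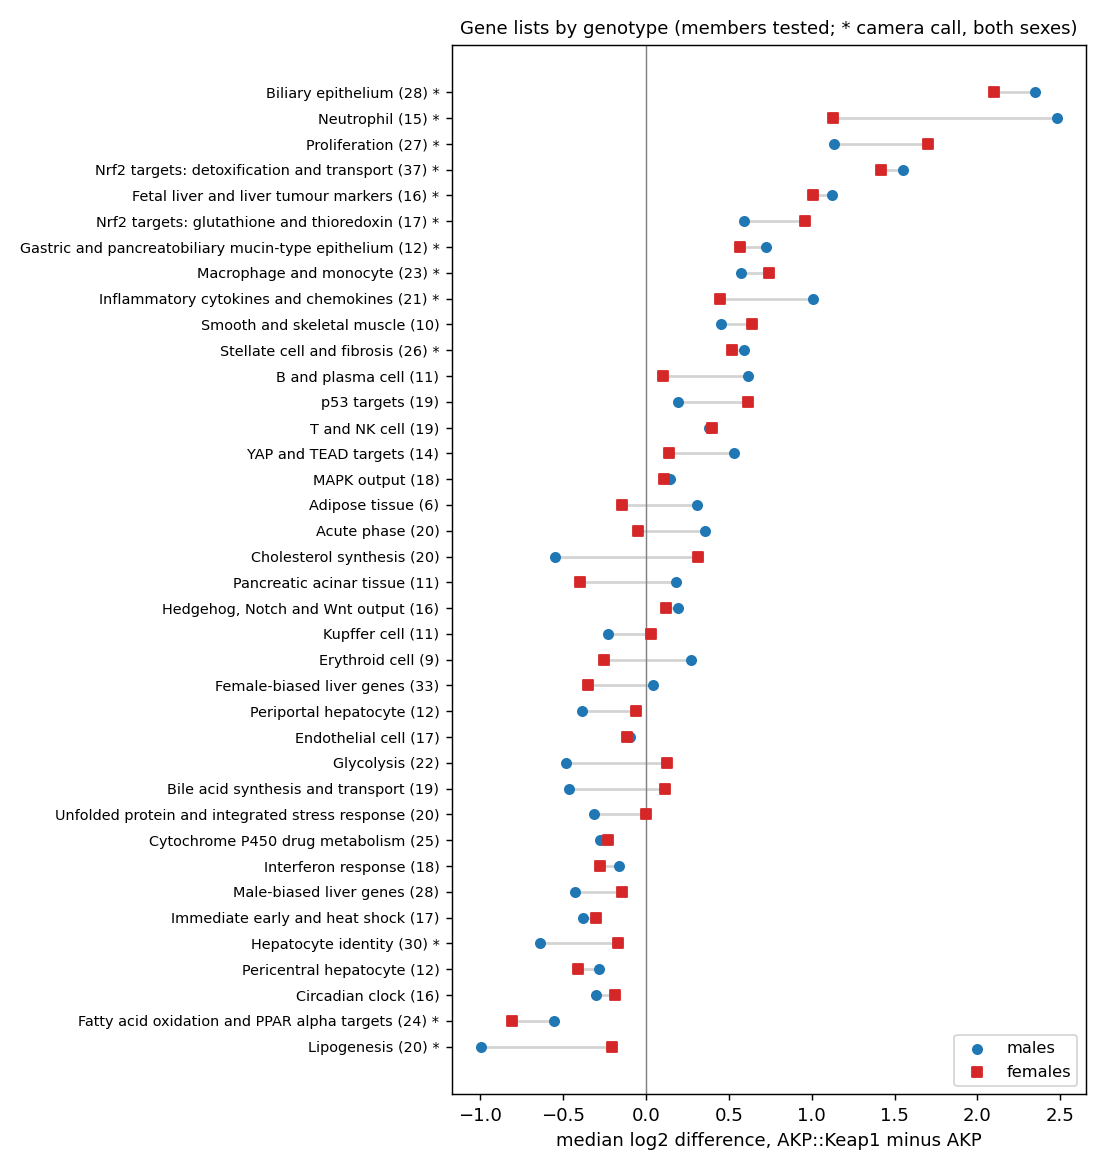
Median log2 difference, AKP::Keap1 minus AKP, of each of 38 gene lists in males (circles) and females (squares), with the number of tested members in brackets and an asterisk where camera called the list over both sexes. The biliary list lies at 2.35 in males and 2.10 in females, and the hepatocyte identity list at -0.64 and -0.17.

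Within each sex S100b, Slc7a11, Gsta1 and Tinag were among the 5 largest fitted rises, while the 5 largest fitted falls among called genes differed. That difference depends on the calls. Cyp4a14, named for females, had -4.73 ± 1.68 in males but was not called there (adjusted p = 0.078). In males 4464 genes were called (2649 higher, 1815 lower), and in females 3390 (1949 higher, 1441 lower). The fitted rises in males were led by S100b (at least 153-fold), Cxcl5 (9.09 ± 0.61), Slc7a11 (at least 68.9-fold), Gsta1 (7.81 ± 0.70) and Tinag (at least 61.0-fold). In females they were S100b (at least 149-fold), Gsta1 (8.72 ± 0.70), Tinag (8.35 ± 0.52, above background on 1 of 2 AKP female arrays), Cbr3 (7.98 ± 0.18) and Slc7a11 (at least 53.9-fold). Fitted falls in males included the intestinal alkaline phosphatase gene Akp3 (at least 3.80-fold), Tmeff2 (-3.66 ± 0.82), Gldn (at least 4.65-fold), Lypd10 (at least 2.84-fold) and the phosphatidate phosphatase Lpin1 (-3.45 ± 0.39). In females they included Cyp4a14 (-6.49 ± 1.68), Slc25a30 (-3.87 ± 0.60), Lipg (at least 3.69-fold), Rnf225 (at least 2.52-fold) and the phosphate transporter Slc34a2 (at least 5.49-fold). In males 1607 genes were called without AKP male 1, 1610 without AKP male 2, 1584 without AKP::Keap1 male 1 and 1033 without AKP::Keap1 male 2. In females 1828 were called without AKP female 1, 729 without AKP female 2, 2240 without AKP::Keap1 female 1 and 1438 without AKP::Keap1 female 2. A fit to the 4 female arrays alone called 1230.

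Across genes, which are not independent replicates, the male and female differences correlated with Pearson's r = 0.69 and Spearman's rho = 0.56. Of 1747 genes called in both sexes, 1695 (97.0%) had the same direction and 52 the opposite one. For same-direction calls, independent lists of these sizes would share 491 genes. That number is no baseline for chance, because the calls of both sexes use the same fitted spread of each gene. A gene with a small spread is therefore more easily called in both. Same-direction calls numbered 763 and 757 without AKP male 1 or 2, 702 and 504 without AKP::Keap1 male 1 or 2, 977 and 425 without AKP female 1 or 2, and 844 without AKP::Keap1 female 2.

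**Figure D3:**
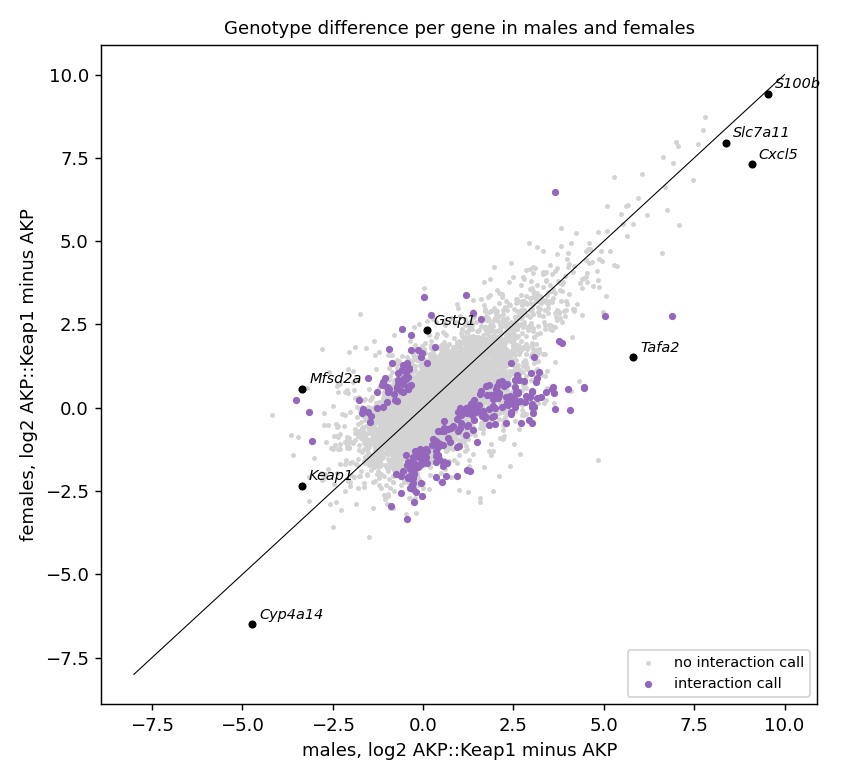
Log2 difference, AKP::Keap1 minus AKP, of each of 15834 genes in males (horizontal) and females (vertical), with equality as a line, the 272 genes of the interaction in purple and some named genes in black. S100b, Slc7a11 and Cxcl5 lie far up in both sexes.

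The genotype by sex interaction asks which genes responded differently to Keap1 loss in females and males. It called 272 genes, 65 higher and 207 lower in the female difference, while a shift to the array median, which moved all genes by a median of 0.25, gave 930 higher and 259 lower, and a trend and robust variance model gave 279 higher and 262 lower. Mfsd2a, a lipid transporter, fell in males (-3.35 ± 0.25) with 0.57 ± 0.25 in females (adjusted p = 0.15), a difference of 3.93 ± 0.35 (adjusted p = 0.017). The kynurenine aminotransferase Kyat3 (3.05 ± 0.32), Gfra4 (3.32 ± 0.42), Lypd10 and Chrdl2 (2.95 ± 0.49, above background on 1 of 2 AKP female arrays) also had higher female differences. Tafa2 (-4.30 ± 0.41), the lens crystallin Cryaa (-4.16 ± 0.48), the transporter Abcc12 (-4.11 ± 0.27), Tbx10 (-3.88 ± 0.31) and the Brca1 partner Bard1 (-3.85 ± 0.32) had lower ones. Of these, Gfra4 and Bard1 have other probes of opposite sign, and Lypd10 was above background only in AKP males, so that its fitted value is no measured size. Gstp1, a glutathione transferase with a value of 0.09 ± 0.15 in males, rose by 2.32 ± 0.15 in females (interaction 2.23 ± 0.21, adjusted p = 0.018). Keap1 itself was not called (1.02 ± 0.21, adjusted p = 0.075).

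Camera called 5 of 38 lists in the interaction. Cholesterol synthesis (20 genes, median 0.75, adjusted p = 0.00087), hepatocyte identity (30 genes, 0.42, adjusted p = 0.011), proliferation (27 genes, 0.58, adjusted p = 0.048) and glycolysis (22 genes, 0.32, adjusted p = 0.048) were higher. Pancreatic acinar genes (11 genes, -0.89, adjusted p = 0.032) were lower. These lists had 0 members called by limma, and adjusted over the list alone 2 cholesterol genes were higher and 1 acinar gene was lower. Members with small p were Mvd (1.87 ± 0.34, adjusted p = 0.060) and Stard4 (1.55 ± 0.31, other probe 0.60), Asl (1.25 ± 0.30), Rrm2 (2.15 ± 0.59) and Pcna (0.58 ± 0.19), Tpi1 (1.01 ± 0.25) and Pgam1 (0.73 ± 0.20), and Clps (-2.19 ± 0.40) and Rnase1 (-3.13 ± 0.91, with some arrays below background). For each of the 5 lists, adjusted p = 0.942 with an estimated correlation, and fry called 0 lists, with 2 at an unadjusted p below 0.05. After quantile normalization 160 genes and 4 lists were called, cholesterol synthesis and proliferation among them and the other 3 lists not. The proliferation call ended after a median shift and, with that of glycolysis, without the background filter, and the acinar and glycolysis calls with genes above background on all 8 arrays. Without AKP male 1 or 2, 32 and 0 genes and 4 and 3 lists were called, and without AKP::Keap1 male 1 or 2, 51 and 3 genes and 9 and 4 lists. Without AKP female 1 or 2 there were 4 and 2 genes and 7 and 2 lists, and without AKP::Keap1 female 1 or 2, 0 and 0 genes and 3 and 4 lists. Cholesterol synthesis kept its call whichever 1 array was left out. Hepatocyte identity lost it without AKP::Keap1 female 1 (0.28), and proliferation without AKP male 2 (0.46), AKP::Keap1 male 2 (0.54), AKP female 2 (0.67) or AKP::Keap1 female 1 (0.23). Acinar genes lost it without AKP male 2 (-0.83), AKP::Keap1 male 1 (-0.98), AKP female 2 (-0.48) or AKP::Keap1 female 2 (-1.29), and glycolysis without these arrays (0.32, 0.28, 0.31 and 0.37) or AKP male 1 (0.25).

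**Figure D4:**
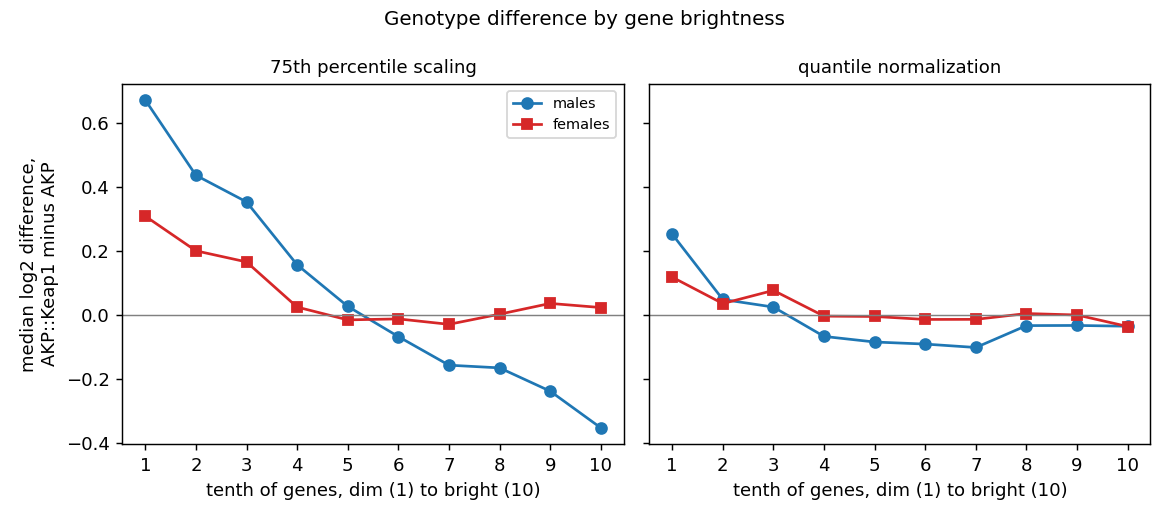
Median log2 difference, AKP::Keap1 minus AKP, in 10 equal groups of genes ordered from dim (1) to bright (10) by their mean over all arrays, for males (circles) and females (squares), after the 75th percentile scaling (left) and after quantile normalization (right). In males the left panel runs from 0.67 to -0.35, and the right one from 0.25 to -0.03.

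Sex differences matched the labels of all 8 mice. The probes used for the Y-linked genes Ddx3y (at least 302-fold, adjusted p = 3.6e-07), Eif2s3y (at least 768-fold, adjusted p = 2.7e-06) and Uty (at least 9.40-fold) were well above background on every male array and on no female array. The other Uty probe was above background only on the array of AKP male 1. The probe of the Y-linked gene Kdm5d was above background only on that of AKP male 2 and was not kept. The X-inactivation RNA Xist was higher in females (2.18 ± 0.16, adjusted p = 0.0016), where the probe used was also above background in AKP::Keap1 males, and the other probe was above background on every female and no male array. Kdm6a was higher in females (0.72 ± 0.09), while Kdm5c (-0.14 ± 0.11, other probe 0.13) and Ddx3x (0.11 ± 0.09, other probe 0.75, and -0.080 with series matrix values for the probe used) were not called. The probes of Eif2s3x disagreed, at 1.42 and -1.78.

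Between sexes, averaged over the genotypes, 3348 genes were called, 1724 higher and 1624 lower in females, and 849 changed at least 2-fold. Among the largest female excesses were those of the sulfotransferases Sult2a6 (at least 3315-fold), Sult2a1 (12.45 ± 0.15), Sult2a2 (12.13 ± 0.20), Sult2a4 (11.84 ± 0.59) and Sult3a1 (at least 310-fold), a family of similar sequence whose single values are uncertain. Cyp3a44 (9.32 ± 0.51), Hao2 (9.22 ± 0.37), Slc22a26 (8.75 ± 0.62) and A1bg (at least 42.6-fold) followed. The male excesses, apart from the Y-linked genes, included the steroid enzyme Hsd3b5 (-10.34 ± 0.46), Cyp4a12b (-8.90 ± 0.27), Nat8f5 (at least 146-fold), Cyp4a12a (-7.88 ± 0.32), Pax2 (-6.80 ± 0.56, other probe -0.80), Elovl3 (-6.76 ± 0.55), the organic anion transporter Slco1a1 (-6.39 ± 0.39) and complement factor D, Cfd (-5.55 ± 0.73). On the dim side, Hao2 and Cfd were above background on 1 of 4 arrays, Sult2a1, Sult2a2, Sult2a4 and Slc22a26 on 2, and Hsd3b5 and Elovl3 on 3, so that their sizes are uncertain. Of 33 female-biased liver genes fixed beforehand, 25 rose in females, 0 fell and 8 were not called (28 rose adjusted over the list alone), with a median of 2.01. Of 28 male-biased genes, 0 rose, 22 fell and 6 were not called (24 fell adjusted over the list alone), with a median of -2.70. Camera called both (adjusted p = 3.2e-17 and 1.4e-18), each with adjusted p = 0.496 with an estimated correlation.

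Immune markers were also higher in females. Of 19 T and NK cell genes, 11 rose, 0 fell and 8 were not called (15 rose and 1 fell adjusted over the list alone), with a median of 0.82, led by Il7r (0.95 ± 0.10), Ncr1 (at least 1.80-fold) and Klrk1 (1.21 ± 0.15). Of 11 B and plasma cell genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.76, among them Cd79a (1.14 ± 0.15, above background on 1 of 4 male arrays) and Fcer2a (0.75 ± 0.10), and Derl3 fell (-1.76 ± 0.47). Of 18 interferon response genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.54, such as Gbp2 (1.69 ± 0.22), Gbp3 (1.34 ± 0.22) and Cxcl10 (1.02 ± 0.18). Camera called them at adjusted p = 4.4e-05, 0.0017 and 0.00061, each with adjusted p = 0.799 with an estimated correlation. Of 27 proliferation genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.63 (adjusted p = 0.00029, and adjusted p = 0.808 with an estimated correlation), among them Bub1b (1.13 ± 0.18) and Mcm5 (0.88 ± 0.16), and Ccne1 fell (-1.66 ± 0.36).

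Of 25 P450 genes, 10 rose in females and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.020, and adjusted p = 0.808 with an estimated correlation), with Cyp3a44 and Cyp2b13 (7.39 ± 0.83) higher and Cyp1a1 lower (-0.97 ± 0.22). Genes of the unfolded protein and integrated stress response were lower in females: of 20, 1 rose and 7 fell (1 and 9 adjusted over the list alone), with a median of -0.34 (adjusted p = 0.020, and adjusted p = 0.799 with an estimated correlation), among them the chaperone Hspa5 (-0.64 ± 0.10), Creld2 (-1.49 ± 0.25) and Sdf2l1 (-0.90 ± 0.16), and Sesn2 rose (0.63 ± 0.11). Camera called 13 of 38 lists by sex, of which fry called 4, those of male-biased, female-biased, T and NK cell and endothelial genes. Males and females were scanned on different days, so sex and scan day cannot be told apart. With the slide as a random block, 326 genes were called by sex. Without 1 array there were 1275 (AKP male 1), 2187 (AKP male 2), 1594 (AKP::Keap1 male 1), 1117 (AKP::Keap1 male 2), 1235 (AKP female 1), 2131 (AKP female 2), 2196 (AKP::Keap1 female 1) and 1875 (AKP::Keap1 female 2). The P450 call ended without AKP female 1, where the median was 0.25, and the stress response call without AKP::Keap1 male 2, where it was -0.20, and with series matrix values.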

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

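The tests on brightness, on scaled negative control signals and on olfactory receptor genes in this part were chosen after the results were seen, and the test on raw negative control signals before. The difference between the sexes in the response to Keap1 loss stands out because the interaction itself was tested. It called 272 genes.

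Of the 272 genes, 207 were lower in the female than in the male genotype difference. After quantile normalization 73.8% of the calls were still lower. This share does not decide on scaling that varies with brightness, because that normalization reduced the trend without removing it among dim genes. The interaction median of the dimmest 1584 genes went from -0.33 to -0.13, and that of the brightest 1584 from 0.38 to -0.0013. Such scaling therefore stays open as a cause. A raised non-specific signal on the slide of the AKP::Keap1 males stays open. The 287 olfactory receptor genes kept had an interaction median of -0.42 (-0.22 after quantile normalization, -0.18 after a median shift and -0.81 with series matrix values). This median decides nothing, because a gene could pass the filter through the 2 AKP::Keap1 male arrays alone. The dimmest 1584 of all genes also had a negative median, -0.33. Raw negative control signals were 44.0 on both AKP::Keap1 male arrays against 39.0 to 42.0 on the others, with 6 of 6 other arrays below both. Local background at these spots was 32.0 and 30.0 on those 2 arrays and 23.0 to 30.0 on the others. The raw signals alone therefore do not show a rise above local background. After background subtraction and scaling 2 of 6 other arrays lay below both, which decides nothing, because subtraction leaves these spots near 0 (1.92 to 3.23) on every array; a true difference between the sexes in the response to Keap1 loss, which the design names, also stays open and untested, since each slide holds 1 group. The lower majority does not hold under a shift to the array median, with 930 higher and 259 lower calls, or under a trend and robust variance model, with 279 higher and 262 lower.

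The called lists of the interaction were set against 10000 random lists matched on brightness. The hepatocyte identity list (median 0.42) lay at percentile 69.1 and the glycolysis list (0.32) at percentile 85.3, so brightness alone may give these medians. The cholesterol synthesis list (0.75) and the proliferation list (0.58) lay at percentile 100, and the pancreatic acinar list (-0.89) at percentile 0.52, which argues against brightness as the whole cause for them. The acinar call ended after quantile normalization with a median of -0.67, while the cholesterol and proliferation medians were 0.53 and 0.66 and called, although the proliferation call ended after a median shift and without the background filter. A sex difference in the response remains open for these lists, as does the slide.

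Single genes of the interaction are given as values. Higher in the female difference were Mfsd2a (3.93), Gfra4 (3.32), Kyat3 (3.05), Chrdl2 (2.95), Ggt1 (2.83), Gstp1 (2.23), Hspb1 (1.53), Susd4 (1.28) and Gstm2 (1.06). Lower were Tafa2 (-4.30), Cryaa (-4.16), Abcc12 (-4.11), Tbx10 (-3.88), Bard1 (-3.85), Il1a (-1.58), Pparg (-1.49), Mup3 (-1.34) and Idh1 (-1.25). Ggt1, Gstm2, Gstp1, Hspb1, Idh1, Il1a, Mup3, Pparg and Susd4 are the called members of fixed lists, and the Gst and Mup genes among them belong to families of similar sequence. Lypd10 was below background in 3 of 4 groups and Ggt1 in both AKP groups, so the fitted values of Lypd10 (3.74) and Ggt1 are no measured sizes.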

How the results depend on the processing

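The median-signal normexp setting and the additive model with slide as a random block were chosen after seeing the data. Slide as a block in the group fit was not run, because each slide holds 1 group. Of 294 named gene results, 152 kept direction and call under all settings, 128 of the 278 called lost the call under at least 1, and 3 called and 3 uncalled ones changed sign. The list counts by genotype stayed between 12 and 18 except for 0 with an estimated correlation. Without the background filter 118 genes were called in the interaction, and with only genes above background on all 8 arrays 421 and 3 lists. The cause was not tested for any change below, except that testing every probe on its own adds tests.

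Calls by genotype numbered 11019 over single probes and 3310 with the slide block. In males there were 8232 after a median shift and 7417 over probes, and in females 6311 over probes and 1230 from 4 arrays. In the interaction there were 410 with normexp, 160 with quantile normalization, 1189 with a median shift, 460 with series matrix values, 605 over probes and 541 with trend and robust eBayes. By sex there were 5954 over probes, 1446 in the additive model and 326 with the slide block. Lists called in the interaction numbered 9 after a median shift, 0 with an estimated correlation and 0 with fry, and by sex 0 and 4. At an unadjusted p below 0.05, camera with an estimated correlation had 1 list by genotype, 0 in the interaction and 3 by sex, and fry 2 in the interaction.

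Deviations of equal replicate numbers correlated between -0.16 and 0.12 across genes, which are not independent. With 2 mice per group this shows no clear pairing by number and cannot exclude one. Replicate 1 lay at position 1 and replicate 2 at position 2 of each slide, so the replicate block also stands for position. With the replicate block 59 interaction genes were called, and no other count moved by over 1.5 times.

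The share of higher calls moved with scaling, and in the interaction also with trend and robust eBayes, to 51.6%, and with genes above background on all 8 arrays, to 34.2%. Without AKP male 1 or 2, or AKP::Keap1 male 1 or 2, it was 79.2%, 74.8%, 76.5% and 79.9% in males, and in the interaction it was 12.5% without AKP male 1 and 7.84% without AKP::Keap1 male 1, the others having at most 4 calls. In the settings used it was 55.9% by genotype, 59.3% in males, 57.5% in females, 23.9% in the interaction and 51.5% by sex. After a median shift it was 27.1%, 20.8%, 40.2%, 78.2% and 31.6%, with all genes shifted by -0.25, -0.39, -0.08, 0.25 and -0.10. With series matrix values it was 89.8%, 97.0%, 72.5%, 3.26% and 16.6%, with shifts of 0.31, 0.48, 0.16, -0.38 and -0.20, and with normexp 37.8% in the interaction.

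Sign changes with series matrix values were Hmox1 (0.093), Nr1h3 (0.0093), Postn (0.0023) and by sex Ddx3x (-0.080), and in list medians glycolysis in the interaction (-0.068) and endothelial cells by sex (-0.0039). Trp53 turned to -0.11 with quantile normalization and -0.12 with a median shift, Eif2s3x by sex to -0.18 with the mean of probes, and the hepatocyte list in the interaction to -0.0042 with normexp. Hmox1 ranged from -0.46 to 0.029 without 1 array.

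Without 1 array, each lone mouse being assumed to vary like the others, calls ranged from 4132 to 5459 by genotype, 1033 to 4289 in males, 729 to 2814 in females, 0 to 51 in the interaction and 1117 to 2196 by sex. Where the interaction had 0 calls in limma (without AKP male 2 or either AKP::Keap1 female), 3036 to 3633 genes had an unadjusted p below 0.05. Shared calls of the sexes ranged from 425 to 1392, and called lists from 12 to 16 by genotype, 2 to 9 in the interaction and 12 to 14 by sex.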

Other observations

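Among lists that camera did not call by genotype, single genes of signalling pathways changed. Of 19 p53 targets, 5 rose, 3 fell and 11 were not called (6 rose and 3 fell adjusted over the list alone, median 0.34), with Phlda3 (1.53 ± 0.20) and the apoptosis gene Pmaip1 (1.43 ± 0.23) higher and Ei24 (-1.14 ± 0.13) and Btg2 (-0.72 ± 0.10) lower. Of 18 MAPK output genes, 3 rose, 3 fell and 12 were not called (the same adjusted over the list alone, median 0.20): Etv4 (1.74 ± 0.28) and the phosphatase Dusp4 (1.20 ± 0.34) rose, and Dusp5 (at least 1.63-fold) and Dusp6 (-0.63 ± 0.13) fell. Of 14 YAP and TEAD targets, 5 rose, 1 fell and 8 were not called (5 and 1 adjusted over the list alone, median 0.25), with Ankrd1 at 2.17 ± 0.41 and Gadd45b at 1.24 ± 0.19. Of 16 Hedgehog, Notch and Wnt genes, 6 rose, 3 fell and 7 were not called (6 and 3 adjusted over the list alone, median -0.03). The Notch ligand Jag2 (at least 2.15-fold), Nrarp (1.15 ± 0.19) and Hey1 (0.72 ± 0.11) rose, and Tcf7 (-1.09 ± 0.18) and Ptch1 (at least 1.81-fold) fell.

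Single genes of metabolic lists changed, while camera did not call these lists and fry called glycolysis (adjusted p = 0.034). Of 22 glycolysis genes, 5 rose, 6 fell and 11 were not called (5 and 7 adjusted over the list alone, median -0.21). The liver pyruvate kinase Pklr (-1.91 ± 0.13) and the glucose transporter Slc2a2 (-1.09 ± 0.13) fell, while the hexokinase Hk1 (1.31 ± 0.21, other probe 0.48) and the lactate transporter Slc16a3 (1.09 ± 0.15) rose. Of 20 stress response genes, 4 rose and 5 fell (the same adjusted over the list alone, median -0.24): the serine and asparagine synthesis genes Phgdh (1.49 ± 0.22) and Asns (2.39 ± 0.54) rose, and the chaperones Hspa5 (-0.43 ± 0.10) and Hsp90b1 (-0.68 ± 0.12) fell. Of 19 bile acid genes, 5 rose and 3 fell (the same adjusted over the list alone, median -0.24), with Cyp8b1 (2.16 ± 0.37) and the efflux pump Abcc3 (0.99 ± 0.16) higher and the uptake carriers Slco1b2 (-0.66 ± 0.09) and Slco1a1 (-1.78 ± 0.39) lower. Pancreatic acinar genes were mixed (2 rose, 2 fell of 11, median 0.02), with the elastase Cela1 at 3.55 ± 0.23. Fry called the pericentral (adjusted p = 0.023) and muscle lists (adjusted p = 0.049). The medians of the remaining lists that camera did not call were -0.47 for pericentral and -0.18 for periportal hepatocyte genes, -0.09 for erythroid, 0.13 for adipose and 0.49 for muscle genes. They were 0.04 for acute phase, -0.33 for interferon, 0.02 for cholesterol synthesis, -0.29 for P450, -0.43 for immediate early and heat shock, and -0.62 for clock genes. The mean had the opposite sign to the median in the Hedgehog, Notch and Wnt (0.21), stress response (0.12), bile acid (0.23), periportal (0.05), adipose (-0.01) and cholesterol (-0.06) lists. Male-biased liver genes had a median of -0.35 (3 rose, 9 fell) and female-biased ones of -0.18 (6 rose, 4 fell).

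By sex, camera also called stellate cell (median 0.36, 7 rose, 1 fell), macrophage (0.39, 3 rose, 1 fell), Kupffer cell (0.54, 2 rose, 0 fell), endothelial (0.19, 2 rose, 0 fell) and cytokine genes (0.53, 5 rose, 1 fell) as higher in females. With an estimated correlation the adjusted p was 0.799, 0.899, 0.799, 0.591 and 0.799. Without AKP male 1 the macrophage call ended (median 0.27), and without AKP::Keap1 male 1 or AKP::Keap1 female 2 the macrophage (0.27 and 0.21), endothelial (0.17 and 0.14) and cytokine calls (0.31 and 0.37). Without AKP female 1 the macrophage (0.35) and Kupffer calls (0.56) ended, and without AKP female 2 the endothelial call (0.17). The endothelial call also ended with series matrix values (median -0.0039) and the cytokine call with normexp. The lymphocyte and interferon lists were higher in females too, and scan day as a cause cannot be told apart from sex, because 0 of 2 scan days held both sexes. Within females as within males, all arrays of a sex share a day.

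The tests on the lists that follow were chosen after the results were seen, and the splits of the samples before. In AKP::Keap1 livers the hepatocyte identity list was lower (median -0.44) and the biliary list higher (2.12). A smaller share of hepatocytes that raises all other cell types alike is argued against as the whole cause. The higher of the endothelial and Kupffer medians was -0.074, below the biliary list's lower quartile of 0.72. Lists of other cell types were not used in this comparison. Their medians were 1.94 for neutrophils, 0.66 for macrophages, 0.46 for stellate cells and 0.45 for B and plasma cells. They were 0.33 for T and NK cells and -0.09 for erythroid cells. A smaller share in which the other cell types changed unequally is not covered, because this comparison assumes an equal rise. A scaling that varies with brightness as the whole cause is argued against by the hepatocyte list's position at percentile 0.01 of 10000 random lists matched on brightness. An expansion of duct-like tumour cells, with or without loss of hepatocyte function, may fit these values and was not tested.

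The genotype and sex results were set against other splits of the 8 arrays into 4 and 4, with the other factor in the model, which leaves 34 splits that can be fitted. Only the real split by genotype, 1 of 34, called as many genes as it did, 4842 in this additive model, and the highest other split called 0 in limma (at most 2207 at an unadjusted p below 0.05). For sex, 1 of 34 splits, the real one, called 1446 genes, and the highest other called 1. For both counts the real split called the most genes of the 34 splits. That argues against chance assignment of single arrays, but 34 splits are too few to exclude it. This does not cover slides or scan days, which go with the groups, and in the other splits the real differences add to the residual spread, which lowers their counts.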
